A study of Mus musculus with 6 samples.

How the data were processed

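Chromatin from C3H10T1/2 cells, a line of multipotent mesenchymal cells derived from mouse embryos, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq). The cells stably expressed FLAG-HA-tagged histone H3.3, either wild type or with the K36M change, which replaces lysine by methionine, and were used at passages 10 to 15. Per the labels' protocols, chromatin was digested with micrococcal nuclease to mononucleosomes, 5% was kept as input, and the remainder was precipitated with antibodies to H3K36me3 or H3K27me3. The series holds 6 libraries, made up of 2 inputs and 4 ChIP libraries, with 1 library per antibody and genotype. There are therefore no replicates.

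The data used are 2 peak lists, 1 per mark, as deposited by the authors. Each list has 3 columns, which are the chromosome, the start and the end of each peak, and it carries no peak height, enrichment, p-value or read number. Reads were aligned with Bowtie 1.0.0 to the mouse build mm9, per the submitters' processing notes. The peak caller, its settings, the use of the input libraries, and the genotype or genotypes behind each list are not given in the sources used here. Wild-type and K36M cells are therefore not compared, and the depth behind each peak is unknown. In both lists each start is a multiple of 200 bp and each end lies 1 bp before a multiple of 200 bp. The peaks were therefore read as runs of 200 bp windows counted from 0, with both ends included, and positions are printed counted from 1. The smallest gap between neighbouring peaks was 1.2 kb in the H3K36me3 list and 10.2 kb in the H3K27me3 list, and the shortest peak was 1.2 kb in both, a pattern that joining windows over a different gap for each mark would leave. Gene names were not assigned, because the gene table at hand is on another assembly (GRCm38) and coordinates were not converted. The gene lists fixed beforehand were not analysed here for the same reason.

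Everything else was computed from the positions. The number of peaks, their lengths and the bases covered were taken per list. Overlap was the number of peaks that shared at least 1 bp with a peak of the other list. It was set against 1000 random rotations of the tested list around each chromosome, which keep peak lengths and spacing. The circle was the span from the lowest to the highest position of either list on that chromosome, plus an empty 20 kb at the seam. Rotation p-values are two-sided by doubling, and 0.002 is the smallest they can give. Median lengths were compared by a two-sided permutation test over peaks with 100000 resamples, for which 1e-05 is the smallest p. The share of each list on each chromosome was given with an exact (Clopper-Pearson) 95% interval and compared by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 20 chromosomes. Shares of bases were compared by permuting chromosome labels over peaks 10000 times, with the same adjustment. Clustering was the share of gaps to the next peak of the same list under 10 kb, set against 1000 uniform placements, in which peaks of the list can overlap. Peaks are not biological replicates, so all p-values and intervals describe the arrangement of these lists and not the variation between cultures.

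These comparisons, their alternatives and the rule for the regions named were fixed before the data were examined. The alternatives were joining peaks closer than 1 kb or 5 kb, keeping only the longer peaks, requiring 50% of the shorter peak, counting peaks within 1 kb or 10 kb, uniform placement, autosomes only, bases in place of peaks per chromosome, and gaps of 2 kb or 50 kb. As no gene names could be had, the rule named the 5 longest peaks of each list, the 5 longest runs of clustered peaks and the 5 H3K27me3 peaks with the most shared bases. Chosen after seeing the data were the coverage profile outside peak edges, the comparison of length classes, the shifts of 100 kb to 1 Mb, the nearness of peaks that share no base, placement without overlap at no less than the smallest gap of the list, and the joining of H3K36me3 peaks closer than 10.2 kb. The profile gives the share of bases outside the peaks of the listed mark that the other mark covered. Its standard error is a jackknife over 20 chromosomes, and it was tested by a two-sided permutation of signs over chromosomes with 20000 draws, with Benjamini-Hochberg adjustment over 16 bins. Length classes were adjusted over 3 classes. For nearness, positions nearby were all those in steps of 200 bp from 100 kb to 1 Mb either way within the span, tested by permutation of signs over chromosomes with 20000 draws. Places in gaps were drawn 1000 times for all peaks of a gap together, without overlap and at no less than the smallest gap of their list.

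The rotation procedure was tested on simulated data with 200 rotations each. It called 1 of 40 unrelated list pairs, and recovered 5 of 5 lists made to avoid H3K36me3 peaks and 5 of 5 made to share their places. Of 40 sets of peaks placed at random in gaps, the gap comparison called 3, and a list moved to random positions nearby had a ratio of 1.04 to its own positions nearby. The unrelated lists were rotations of the H3K27me3 list, and the sets in gaps came from the same placement as their comparison. Few calls were therefore built in. These counts check the computation, not whether rotation or placement suits the real lists. The analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.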

Results

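The series profiled H3K36me3 and H3K27me3 in C3H10T1/2 mesenchymal cells that expressed wild-type or K36M mutant histone H3.3. H3K36me3 is known as a mark of the bodies of transcribed genes, and H3K27me3 as the mark laid down by Polycomb repressive complex 2 at silent genes. The 6 libraries consisted of an input, an H3K36me3 and an H3K27me3 library for each genotype. The positions of the called peaks were available as 1 list per mark, on the build mm9 and without a genotype. The comparisons below are therefore between the marks, and no value is given for K36M against wild type.

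As listed, H3K27me3 occupied fewer and broader regions than H3K36me3. The H3K27me3 list held 3999 peaks that covered 238 Mb, or 9.33% of the span between the outermost peaks, and the H3K36me3 list held 7773 peaks that covered 156 Mb, or 6.13%. The median H3K27me3 peak was 24.4 kb long (interquartile range 5.4 to 83.2 kb), against 15.0 kb (8.0 to 26.2 kb) for H3K36me3. H3K27me3 peaks were spread over a wide range of lengths, with more peaks than H3K36me3 at both ends of it. There were 939 H3K27me3 peaks under 5 kb, 23.5% of the list, against 902 H3K36me3 peaks, 11.6%. Peaks of 100 kb and longer numbered 838 for H3K27me3 (21.0%), and these held 66.4% of the bases it covered, whereas 27 H3K36me3 peaks (0.347%) reached that length.

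The difference of 9.4 kb between the median lengths was larger than any of 100000 permutations gave (permutation test over peaks, p = 1e-05). The H3K27me3 median was the longer in 19 of 20 chromosomes, the exception being chromosome 18 (12.6 against 18.4 kb). With peaks closer than 5 kb joined, the H3K36me3 median was the longer on chromosome 3 as well (17600 against 14900 bp). After H3K36me3 peaks closer than 10.2 kb, the smallest gap of the H3K27me3 list, were joined, 5861 H3K36me3 peaks remained. Their median was 20 kb and the difference was 4.4 kb (permutation test, p = 1e-05).

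**Figure D1:**
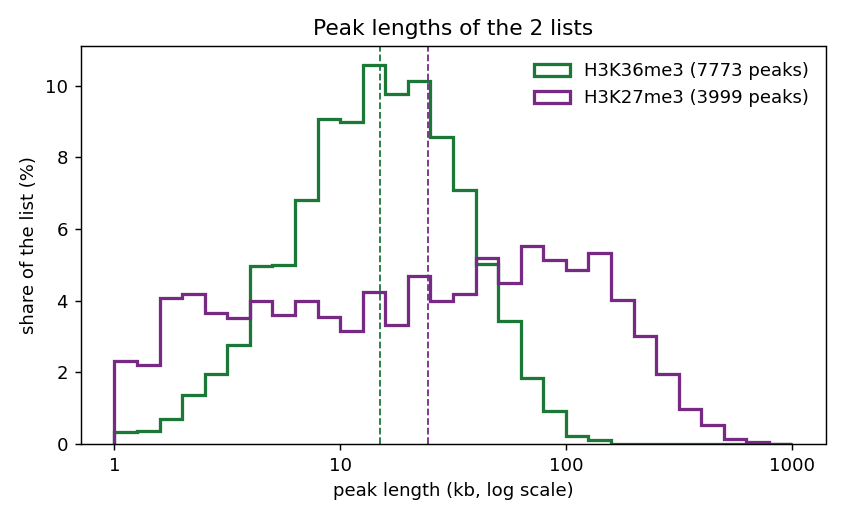
Distribution of peak lengths (kb, log scale) as the share of each list in percent, for 7773 H3K36me3 and 3999 H3K27me3 peaks, with dashed lines at the medians of 15.0 and 24.4 kb. The H3K36me3 lengths form a single hump, and the H3K27me3 lengths extend from 1.2 to 763 kb without one.

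The longest H3K27me3 peak covered 763 kb of chromosome 8, from 11843601 to 12607000. The next was a peak of 654 kb on chromosome 1, from 170770201 to 171424600. Chromosome 14 carried a peak of 640.0 kb from 33400801 to 34040800 and another of 623 kb from 34260801 to 34883800. The fifth, of 603 kb, lay on chromosome 6 from 113692001 to 114295000. None of these 5 peaks shared a base with an H3K36me3 peak, although the nearest H3K36me3 peak was 2.2 to 18.6 kb away. The longest H3K36me3 peak was 177 kb, on chromosome 11 from 23219601 to 23396200. It was followed by peaks of 158 kb on chromosome 15 (63896401 to 64054400), 157 kb on chromosome 2 (17987401 to 18144800), 157 kb on chromosome 1 (196487401 to 196644000) and 146 kb on chromosome 14 (68335801 to 68482000). These 5 peaks also shared no base with the other mark, and their nearest H3K27me3 peak was 25 to 410 kb away.

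**Figure D2:**
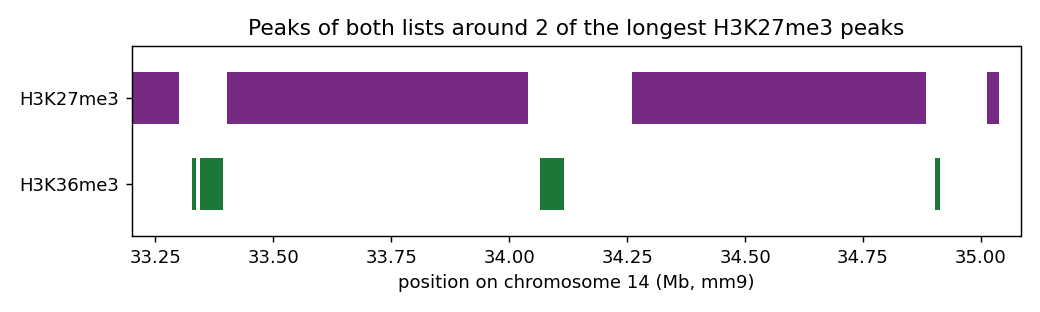
Map of chromosome 14 from 33.2 to 35.1 Mb (mm9), with each peak of the 2 lists drawn to scale as a box in a row per mark. The H3K36me3 peaks lie in the gaps beside the H3K27me3 peaks of 640.0 and 623 kb and share no base with them.

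H3K36me3 and H3K27me3 occupied almost entirely separate bases. Only 57 H3K27me3 peaks (1.43%) shared a base with an H3K36me3 peak, where rotation gave 646 ± 27.7 (SD over 1000 rotations), a ratio of 0.0882 to the expected number. Seen from the other list, 73 H3K36me3 peaks (0.939%) were shared, where rotation gave 993 ± 50.7. The shared bases added up to 381 kb, which is 0.160% of the bases under H3K27me3 and 0.244% of those under H3K36me3, against an expected 15.3 ± 0.853 Mb. All 3 values were below every rotation (permutation by rotation, p = 0.002). The avoidance held in each length class of H3K27me3 peaks. Bases were shared by 8 of 939 peaks under 5 kb where 67.0 were expected, by 28 of 2222 peaks of 5 to 100 kb where 308 were expected, and by 21 of 838 peaks of 100 kb and longer where 270 were expected (permutation by rotation, adjusted p = 0.002 for each). The lists carry no genotype, so it is not known whether both describe the same cells.

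Where bases were shared, the shared stretch was short, with a median of 3.8 kb per H3K27me3 peak, and 45 of the 73 H3K36me3 peaks lay wholly inside an H3K27me3 peak. In the other direction, 7 of the 57 H3K27me3 peaks lay wholly inside an H3K36me3 peak. The most shared bases were in an H3K27me3 peak of 116 kb on chromosome 11 (82985801 to 83101800), of which 5 H3K36me3 peaks took 57.4 kb. An H3K27me3 peak of 53.6 kb on chromosome 17 (6219601 to 6273200) shared 27 kb. The next 3 were on chromosome 14 (75465601 to 75683200), sharing 23.6 kb, on chromosome 10 (21861801 to 22401400), sharing 22.4 kb, and on chromosome X (67608001 to 67968400), sharing 20 kb.

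Many H3K27me3 peaks lay close to H3K36me3 without sharing bases with it. A further 1010 H3K27me3 peaks (25.3%) lay within 10 kb of an H3K36me3 peak in this way, and the median distance to the nearest H3K36me3 peak was 39.0 kb. Of the 3942 H3K27me3 peaks that shared no base, these were 25.6%, against 4.23% ± 0.370 under rotation and 6.85% ± 0.956 under shifts of 100 kb to 1 Mb, which keep the density of the region (permutation by rotation or shift, p = 0.002 for both). Rotated and shifted peaks that share no base may be those that fall where H3K36me3 is sparse, so the peaks were also compared with positions 100 kb to 1 Mb away at which the same peak would share no base. These positions carry the same condition, so avoidance of sharing could by itself raise the observed share above theirs. For the 3936 peaks that had such positions, 7.61% of these lay within 10 kb on average, and the observed share was 17.9 ± 1.07 percentage points higher (jackknife SE) and above it in 20 of 20 chromosomes (permutation of signs, p = 5e-05, the smallest possible). When the peaks were placed at random within the gaps between H3K36me3 peaks that hold them, 17.7% ± 0.440 lay within 10 kb, against 25.7% observed for the 3904 peaks in gaps that no sharing peak entered (ratio 1.45, permutation by placement, p = 0.002). In this comparison the ratio was 1.72 for peaks of 100 kb and longer and 1.48 for peaks of 5 to 100 kb (permutation by placement, adjusted p = 0.003 for both), whereas for peaks under 5 kb 15.3% were observed and 14.4% ± 0.859 expected (ratio 1.06, adjusted p = 0.33 by the same permutation). Of the 7700 H3K36me3 peaks that shared no base, 1046 (13.6%) lay within 10 kb of an H3K27me3 peak, against 3.29% ± 0.243 under rotation (permutation by rotation, p = 0.002), 5.87% on average at positions 100 kb to 1 Mb away without sharing (above in 20 of 20 chromosomes, permutation of signs, p = 5e-05) and 10.5% ± 0.265 at random places in the same gap (13.6% observed for 7634 peaks, permutation by placement, p = 0.002). With sharing peaks counted as near, the numbers within 10 kb pool the avoidance with this nearness. For H3K36me3 they were 1119 against 1218 ± 52.5 under rotation (permutation by rotation, p = 0.072), and for H3K27me3 1067 against 788 ± 31.1 under rotation (p = 0.002) and 1158 ± 102 under shifts (p = 0.42, both by permutation).

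Coverage by H3K36me3 changed with the distance from the H3K27me3 edge. It was 0.517% ± 0.124 (jackknife SE, 20 chromosomes) within 2 kb outside the edge, 3.23% ± 0.245 from 2 to 5 kb, and 10.1% ± 0.552 from 5 to 10 kb. It reached 16.7% ± 0.661 from 20 to 50 kb and then declined to 10.1% ± 0.594 from 500 to 1000 kb. Coverage from 20 to 50 kb was above that at 500 to 1000 kb in 20 of 20 chromosomes, and coverage within 2 kb was below it in all 20 (permutation of signs over chromosomes, adjusted p = 6.67e-05 for both, from the smallest p of 5e-05 that the draws can give). A peak that shares no base with the other mark covers bases beside its edge only if it ends there. Low coverage near edges therefore follows in part from the avoidance of sharing and the peak lengths, and is not separate evidence of it. H3K27me3 outside H3K36me3 edges stayed below its share at 500 to 1000 kb (15.6% ± 1.00) over a longer stretch. It was 0.773% ± 0.147 within 2 kb and 10.8% ± 0.686 from 10 to 20 kb, and it was highest at 18.0% ± 1.12 from 100 to 200 kb. The H3K27me3 values from 0 to 2 kb and from 10 to 20 kb were below those at 500 to 1000 kb in all 20 chromosomes (permutation of signs, adjusted p = 6.67e-05). The longer stretch cannot be told apart from the greater length of H3K27me3 peaks, which need more room beside an edge. Over all bases outside the peaks of the other mark, coverage was 6.75% for H3K36me3 and 9.93% for H3K27me3. Both shares at 500 to 1000 kb were above these, as was the 10.8% of H3K27me3 from 10 to 20 kb.

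**Figure D3:**
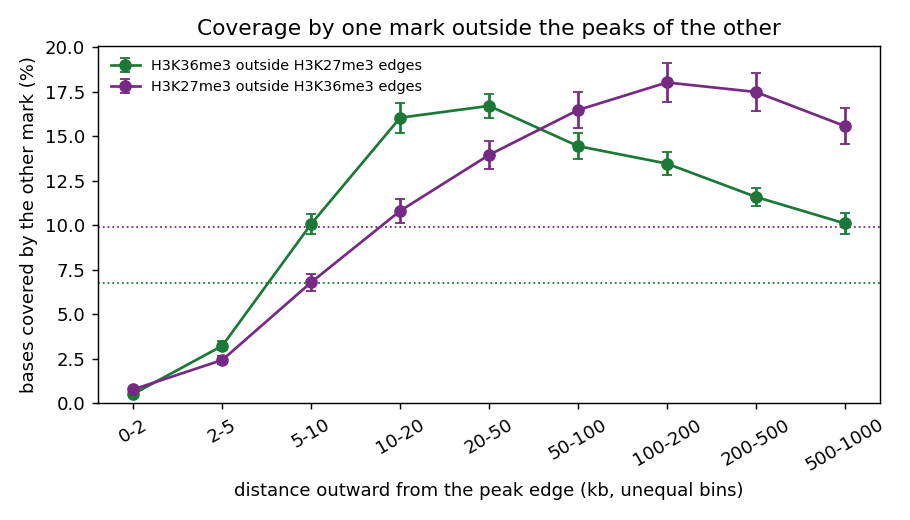
Share of bases covered by the other mark, in percent, against the distance outward from the peak edge in kb (unequal bins), with bars for the jackknife standard error over 20 chromosomes and dotted lines for the share over all bases outside the peaks. Coverage is under 1% within 2 kb of the edges of either mark, and it is highest at 20 to 50 kb for H3K36me3 and at 100 to 200 kb for H3K27me3.

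As listed, H3K36me3 peaks were clustered. The next H3K36me3 peak lay less than 10 kb away for 24.4% of the peaks, against 9.32% ± 0.319 (SD) under uniform placement (permutation by placement, p = 0.002). Uniform placement lets peaks of the list overlap, which the deposited list does not, and placement without overlap, chosen after seeing the data, gave 3.05% ± 0.188 (p = 0.002 by the same permutation). Both placements treat all positions of the span alike, so an uneven density of peaks along the chromosome, whatever its source, also counts as clustering. In all, 3318 H3K36me3 peaks (42.7%) formed 1425 runs of up to 6 peaks. The longest run covered 320 kb of chromosome 15 (63896401 to 64216800) with 4 peaks, and it contained the peak of 158 kb named above. The other 4 were runs of 218 kb on chromosome 2 (115683801 to 115901400), 217 kb on chromosome 9 (70133801 to 70350800), 209.6 kb on chromosome 13 (105079801 to 105289400) and 194 kb on chromosome 7 (89573001 to 89766600), none of which shared a base with H3K27me3. Peaks covered 90.0 to 97.1% of the bases of the runs named here. Gaps in the H3K36me3 list go down to 1.2 kb, so near peaks may be parts of a single marked region listed in pieces. Clustering of separate regions cannot be told apart from such splitting, because the signal between peaks is not listed. No H3K27me3 gap was under 10 kb, as its smallest gap was 10.2 kb. Of the H3K27me3 gaps, 22.5% were under 50 kb, against 7.30% ± 0.395 when peaks were placed without overlap and at least 10.2 kb apart (permutation by placement, p = 0.002).

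The marks were distributed differently over 3 chromosomes. Chromosome 1 held 8.33% of the H3K27me3 peaks (95% interval 7.49 to 9.23) and 6.23% of the H3K36me3 peaks (5.70 to 6.79), with an adjusted p of 0.000292 by Fisher's exact test. Chromosome 11 held 5.93% (5.21 to 6.70) and 8.13% (7.53 to 8.76), with an adjusted p of 0.000259. Chromosome 5 held 5.23% (4.56 to 5.96) and 6.60% (6.06 to 7.17), with an adjusted p of 0.0204. The other 17 chromosomes did not pass the test. Counted as bases instead of peaks, the difference on chromosome 5 did not pass (adjusted p = 0.155), while chromosome 14 carried 5.73% of the H3K27me3 and 3.74% of the H3K36me3 bases and chromosome 18 carried 1.91% and 3.59% (permutation test, adjusted p = 0.00867 for both). Both tests and the intervals treat peaks as independent, whereas peaks of both lists were clustered. The p-values may therefore be too small and the intervals too narrow.

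**Figure D4:**
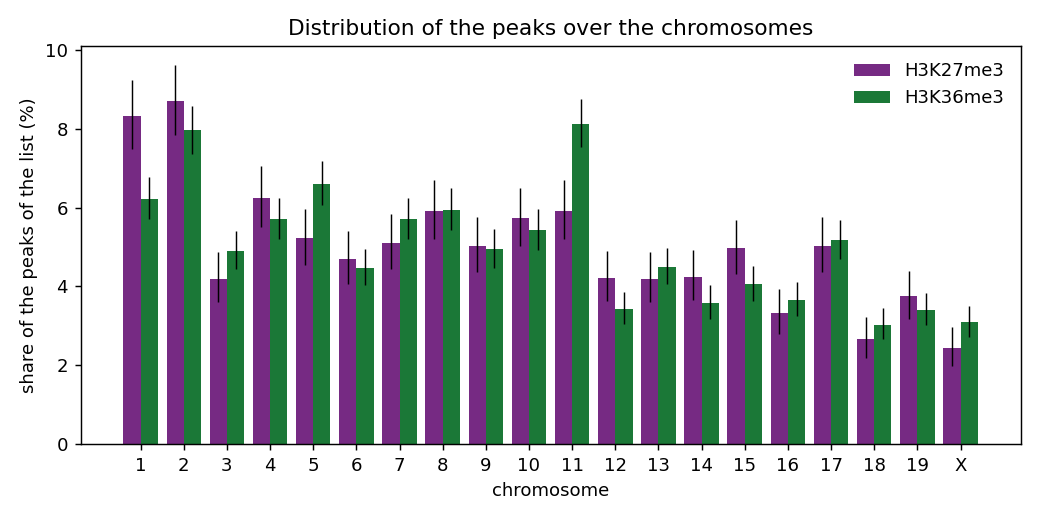
Share of the peaks of each list on each chromosome, in percent, with exact 95% intervals. H3K27me3 stands above H3K36me3 on chromosome 1 (8.33 against 6.23%) and below it on chromosomes 5 and 11 (5.93 against 8.13% on chromosome 11).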

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

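The avoidance of H3K36me3 by H3K27me3 peaks kept its direction and passed the threshold with 50% of the shorter peak required, within 1 kb, with uniform placement, with the longer peaks, in autosomes, against shifts of 100 kb to 1 Mb and with H3K36me3 peaks joined over 10.2 kb (ratios 0.0238 to 0.0977). The shifts and the 10.2 kb joining were chosen after seeing the data. Counting peaks within 10 kb reversed the ratio to 1.35, because it adds 1010 neighbouring peaks, but against the shifts the same count gave 0.921 (permutation p = 0.42). By length class, the ratio to shifts was 0.676 for H3K27me3 peaks of 100 kb and longer (adjusted permutation p = 0.006). It was 1.09 for peaks of 5 to 100 kb and 0.942 for those under 5 kb (adjusted permutation p = 0.62 and 0.69). Because that count pools sharing with nearness, the peaks that share no base were tested by themselves, a choice made after seeing the data. Their share within 10 kb stayed above the expected one against rotation, also with joined H3K36me3 peaks, against shifts, against positions nearby without sharing and against random places in the same gap (ratios 1.45 to 6.11), and so did that of H3K36me3 peaks in each comparison made (1.30 to 4.13). Rotation, shifts and positions nearby carry the condition of no sharing, so avoidance could by itself raise those ratios. For H3K27me3 peaks under 5 kb, the ratio to random places in the same gap was 1.06 (adjusted permutation p = 0.33). Joining peaks closer than 1 kb changed nothing, since no gap is that small, and 5 kb left 6482 H3K36me3 peaks. Keeping the longer peaks left 3886 H3K36me3 and 1999 H3K27me3 peaks by construction. The length difference remained above 0 in all 3 alternatives (4400 to 57000 bp). Of these, joining over 1 kb left the lists unchanged, and the longer peaks compare the upper quartiles of the lists (83.2 and 26.2 kb). Only the joining over 10.2 kb bears on how the lists were made, and it lowered the difference to 4400 bp. Clustering of H3K36me3 turned to 6.77% against 6.93% for gaps under 2 kb (permutation p = 0.65), a comparison that says little because uniform placement counts overlapping peaks as short gaps. Placement without overlap, also chosen after seeing the data, gave 0.283% there and 15.7% under 50 kb, against 47.6% observed. That of H3K27me3, 0% under 10 kb and 2 kb because its smallest gap is 10.2 kb, turned to 22.5% under 50 kb, against 16.7% by uniform placement and 7.30% without overlap. The count of differing chromosomes was 3 by peaks, 4 by bases and 3 after joining over 5 kb. Gene lists and K36M against wild type were not run, and the depth of the libraries is unknown. No paired analysis was possible because the lists name no library and each group has 1 library.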

Other observations

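The tests of shifts, joined gaps, nearness without sharing, bin sizes and line order below were chosen after the main results were seen. H3K36me3 and H3K27me3 avoided each other over short distances and were found in the same parts of chromosomes over long ones. Across 254998 bins of 10 kb, the coverage by the 2 marks had a Pearson correlation of -0.088 (Spearman -0.085), and across 503 bins of 5 Mb it was 0.537 (Spearman 0.618). At 1 Mb it was 0.305 (Spearman 0.542), and at 100 kb the coefficients differed in sign (-0.047 and 0.121). Each lay outside 1000 rotations (permutation p = 0.002, adjusted p = 0.002 over 4 bin sizes, the smallest possible). Bins are neighbours and not independent replicates. Leaving out bins without a peak of either mark lowers the values by construction, so those were set against rotations filtered alike, and the Pearson correlations were -0.775 at 10 kb (-0.677 ± 0.00563 rotated), -0.436 at 100 kb (-0.312 ± 0.00955), 0.155 at 1 Mb (-0.0584 ± 0.0234) and 0.520 at 5 Mb (0.0443 ± 0.0439), each outside the rotations (permutation, adjusted p = 0.002). The Spearman values lay on the same side of their rotations, but at 100 kb -0.632 did not pass (-0.614 rotated, adjusted permutation p = 0.11).

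Chromosome X had the fewest peaks per Mb of both marks. H3K27me3 had 0.612 peaks per Mb there, against 1.08 to 2.59 on the autosomes, and H3K36me3 had 1.51 against 2.28 to 5.33. H3K36me3 covered 2.86% of the X span, below the autosomal range of 4.46 to 10.6%, while H3K27me3 covered 5.24%, within its range of 5.19 to 16.1%. The median H3K27me3 peak on X was 42.5 kb, toward the upper end of the autosomal 12.6 to 47.1 kb. The read depth on X and its copy number in these cells are not known here. Fewer marked regions therefore cannot be told apart from fewer reads on X.

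The separation of the marks was weighed against how the lists were made. A removal of every overlapping peak before deposit is argued against by the 57 peaks that still share bases, although a partial removal stays open. Joining called H3K36me3 peaks over 10.2 kb left a ratio of 0.0927 to rotation, with 60 H3K27me3 peaks sharing bases. Such joining can add sharing only where H3K27me3 peaks reach into H3K36me3 gaps under 10.2 kb. Windows outside called peaks are not listed, so different joining gaps stay open. Occupation of different chromosome regions is argued against by a ratio of 0.0598 against shifts of 100 kb to 1 Mb. H3K27me3 peaks without shared bases lay within 10 kb of H3K36me3 more often than under rotation. Their ratio to positions 100 kb to 1 Mb away without sharing was 3.36, but avoidance together with regions dense in both marks could give such an excess. With sharing peaks counted as near, the ratio to shifts was 0.921 (permutation p = 0.42), so dense regions stay open. Random placement within the same gaps does not explain the nearness in full, given 17.7% expected and 25.7% observed (ratio 1.45). For peaks under 5 kb, the 15.3% observed was close to the 14.4% expected (ratio 1.06). The genotype behind each list stays open, and an antagonism of H3K36 methylation and Polycomb repressive complex 2 remains a hypothesis that these positions cannot separate from choices made in peak calling.

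The greater length of H3K27me3 peaks may owe part of its size to a joining of windows over longer gaps in that list, whose smallest gap is 10.2 kb. With H3K36me3 joined over 10.2 kb, the difference of medians was 4400 bp in place of 9400 bp (permutation p = 1e-05). Joining called peaks does not repeat the calling with that gap, because windows outside the called peaks are not listed. Whether the gap is the whole cause therefore stays open, as do the other settings of the peak caller, which are unknown.

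The H3K36me3 list runs in order of position, with 7753 of 7753 steps within a chromosome upward, whereas in the H3K27me3 list 106 of 202 such steps were upward. The line number of an H3K27me3 peak went with its distance to the nearest H3K36me3 peak, with a Spearman correlation of 0.213 over 3999 peaks (Pearson 0.178 with the logarithm of distance, permutation p = 0.0001, the smallest possible). The median distance was 12.0 kb in the leading 400 lines and 64.2 kb in the closing 399. Sorting by length is argued against by a correlation of -0.121 with length, chromosome composition by a mean correlation of 0.199 within chromosomes (above 0 in 20 of 20), and the length of early peaks by 0.193 within 10 sets of peaks of like length (above 0 in 10 of 10), both of the latter at a permutation p = 0.0005, the smallest possible. A candidate explanation is that the lines follow a value per peak that goes with nearby H3K36me3, such as a change between genotypes, which was not tested.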
